A study of Homo sapiens with 12 samples.

How the data were processed

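RNA from 6 clones of PC9, a human lung adenocarcinoma line with an activating EGFR mutation, was measured on 12 Illumina expression bead arrays, 2 per clone. Per the labels, clone B7 was sensitive to the EGFR inhibitor gefitinib and clones D6, E1, E2, E3 and E6 were tolerant of it. RNA was extracted with a mirVana kit, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The arrays carried 47229 probes.

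The deposited non-normalized file holds scanner signal intensity on a linear scale with the background already subtracted, since 26.6 to 28.4% of the probes on each array lie below 0. Its 12 columns for detection p-values are empty (0 cells filled). The authors' processed values are linear intensity normalized between arrays, with every value under 20 set to 20, and 54.3 to 55.7% of the values on each array stand at that floor. In these values the first B7 array equals its scanner signal above the floor, and the other arrays differ from theirs by a factor that changes with intensity. The labels and headers do not name the authors' normalization method, the scanner software or the background method.

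The comparisons start from the scanner signal. It was corrected by normexp (saddle-point fit) with an offset of 16, quantile normalized between the 12 arrays and put on a log2 scale with limma 3.58.1 in R 4.3.3. The plan had been to use the detection p-values for the correction and the filter. Without them, the noise of an array was taken as the root mean square of its negative values (8.63 to 10.3 intensity units), and a probe counted as detected above 2.33 times that noise, the 1-sided normal p of 0.01. The limit was 20.1 to 24.1 intensity units, and 19302 to 20290 probes passed it per array. A probe was kept when both arrays of at least 1 clone detected it, which left 21912 probes. Probes were matched to genes by the annotation table and its Entrez numbers: 30112 probes had 1 gene, 8 had several and 17109 had none. Each gene was measured by its brightest kept probe over the 12 arrays, and 12250 genes were tested. For the order of neighbouring genes alone, RefSeq gene order on the human GRCh38 assembly was used.

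Tolerance belongs to a clone, so the main test used 1 mean per clone: limma (lmFit and eBayes) on 6 clone means, 5 tolerant against B7, with 4 residual degrees of freedom and the lone B7 assumed to vary like the tolerant clones. Each tolerant clone was also set against B7, and against the mean of the other 4, in 1 limma fit of all 12 arrays with 6 residual degrees of freedom. These array-level p-values measure only the spread between a clone's 2 arrays, which may be technical, since no label says that the arrays came from separate cultures. A moderated F test compared the 5 tolerant clones, and each of the 6 clones was taken in turn as the odd one. All p-values are 2-sided, adjusted by Benjamini-Hochberg within each comparison, and called under 0.05. Before the data were examined, 36 gene lists and the markers of 4 other cell types were written down. The lists were tested with camera (preset correlation 0.01) on the clone means, and beside it with camera at an estimated correlation and with fry, adjusted over the lists.

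The rule for naming genes was also fixed before the data were examined. It takes the 12 genes with the largest and the 12 with the smallest mean difference among those called with the same sign in all 5 clones against B7. It adds, for each tolerant clone against the other 4, the 3 highest and 3 lowest called genes. From each list described it takes up to 4 members with the largest called difference, or the largest 2 as values where none was called. EGFR, MET, AXL, BCL2L11, KDM5A, VIM and CDH1 are given whatever their values. KDM5A is not analysed here, since no probe was assigned to it. Where the gene's probe lay under the detection limit on every array of a group, or of a clone or the other 4, a fold is given as a lower bound, with each dim array set to the higher of its own normalized value and the lowest detected value on it.

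The tests were checked on simulated data. With 1, 2 and 4 log2 units added to values that had the tolerant clones' spread, the clone-level test recovered 11.8, 63.6 and 89.4% of the changed genes. It called 7 unchanged genes, 6.03% of the calls. On other simulated values with no spread between clones, D6 against B7 at the array level recovered 94.1, 100 and 100%, so the 2 tests are not compared on equal terms. Alternatives tried were no background correction, median scaling, the authors' values, no filter, the mean over a gene's probes, an intensity trend, a minimum log2 difference of 1, the replicate number as a block, the clone as a random block, and leaving out each array and each tolerant clone. An offset of 50, 75th percentile scaling and leaving B7 out of the comparison of each tolerant clone with the others were added after seeing the data. The number of arrays and clones limits the precision. Probes without an assigned gene were left out of the comparisons.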

Results

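Expression of 12250 genes was compared between single-cell-derived PC9 clones, 1 sensitive to gefitinib (B7) and 5 tolerant (D6, E1, E2, E3 and E6), each measured on 2 arrays. The series asked which genes mark gefitinib tolerance. Single cells were sorted into plates that received gefitinib or solvent, and the clones were chosen at random among those that grew. Every sample carries the treatment text of 0.4 to 2 µM gefitinib for 14 days. The labels do not settle whether B7 was exposed to the drug or whether the tolerant clones were harvested in it, so response and exposure are confounded. The 75th percentile of the scanner signal was 131 intensity units on average in B7 and 80.2 to 118 in the tolerant clones, highest in E2. The 2 arrays of a clone correlated at 0.995 to 0.997 (Pearson, across genes, which are not independent replicates). Their root mean square SD was 0.14 log2 units, against 0.36 between the tolerant clones. B7 differed from E2 by a root mean square of 0.605 log2 units and from the other tolerant clones by 0.825 to 0.971. E2 differed from D6 and from E1 by 0.653 each, more than from B7, and from E3 and E6 by 0.512 and 0.538.

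Set against B7, the tolerant clones expressed far more RARRES1 and far less IL1B. RARRES1, a retinoid-induced gene (probe ILMN_1800091), was higher by 7.14 ± 0.81 log2 units (SE, 5 tolerant clones against 1, adjusted p = 0.0122), or 141-fold. Its other probes differed by 6.73 and 2.64, and with the mean over its probes it was higher by 5.50. VTCN1, an inhibitory ligand for T cells, was not detected in B7 and was at least 35.7-fold higher in the tolerant clones (adjusted p = 0.0338). UBE2L6, the conjugating enzyme for ISG15, was higher by 4.92 ± 0.49 (adjusted p = 0.00851), and the lysosomal protease CTSH by 4.49 ± 0.53 (adjusted p = 0.0138). The growth factor binding protein IGFBP3 was higher by 5.39 ± 0.92 (adjusted p = 0.0353), the beta-defensin DEFB1 by 5.21 ± 0.84 (adjusted p = 0.0312) and the oxidised lipoprotein receptor OLR1 by 4.84 ± 0.53 (adjusted p = 0.0113). Complement factor D, CFD, was higher by 5.61 ± 1.09 (adjusted p = 0.049) and was detected on 1 of the 2 B7 arrays. PLAAT4, a retinoid-induced acyltransferase, was at least 13.6-fold higher (adjusted p = 0.0363). All 12 genes at this end were higher in each of the 5 clones at the array level, but 3 did not pass between clones. These were IGFBP5 (at least 23.8-fold, adjusted p = 0.109), the carboxylesterase CES1 (at least 17.6-fold, adjusted p = 0.114) and the mucin MUC1 (4.28 ± 0.93, adjusted p = 0.0615). Without E2 all 3 passed (adjusted p = 0.0121, 0.037 and 0.004), and MUC1 also did with median scaling. Other probes differed by 5.44 for IGFBP3, 5.13 for IGFBP5, 3.43 for UBE2L6, 3.25 for CTSH, 2.75 for CES1, and 3.78 and 1.72 for MUC1.

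In the other direction, IL1B (probe ILMN_1775501) stood at 13.74 log2 units in B7 and at a mean of 8.03 in the tolerant clones, a difference of -5.71 ± 0.67 (SE, adjusted p = 0.0134), and IL1A differed by -4.73 ± 0.42 (adjusted p = 0.00734). TERT, the catalytic subunit of telomerase, was detected on both B7 arrays and on 0 tolerant arrays, at least 12.6-fold lower (adjusted p = 0.000903). A second probe of TERT differed by -2.47 and was likewise detected on 0 tolerant arrays. The neurotensin receptor NTSR1 and the phosphodiesterase PDE2A were likewise detected on 0 tolerant arrays, at least 19.7-fold lower (adjusted p = 0.00142) and at least 10.6-fold lower (adjusted p = 0.000903). The peroxisomal oxidase ACOX2 differed by -5.00 ± 0.53 (adjusted p = 0.00997), and SPRY4, a feedback inhibitor of receptor kinase signalling, by -4.21 ± 0.45 (adjusted p = 0.00997), with -1.52 at its other probe. IL1RL1, the receptor for interleukin 33, was at least 14.7-fold lower (adjusted p = 0.00142), the probe used being detected on 0 tolerant arrays. Its other probe, dimmer in B7 and detected on 2 tolerant arrays, differed by -2.34. The other 4 genes at this end were COL13A1, IL13RA2, MARCHF4 and HSD3B1, with differences between -4.38 and -4.58. Each of these 4 and of ACOX2 and SPRY4 was detected on at most 2 of the 10 tolerant arrays, so the size of its difference rests on values near the background.

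**Figure D1:**
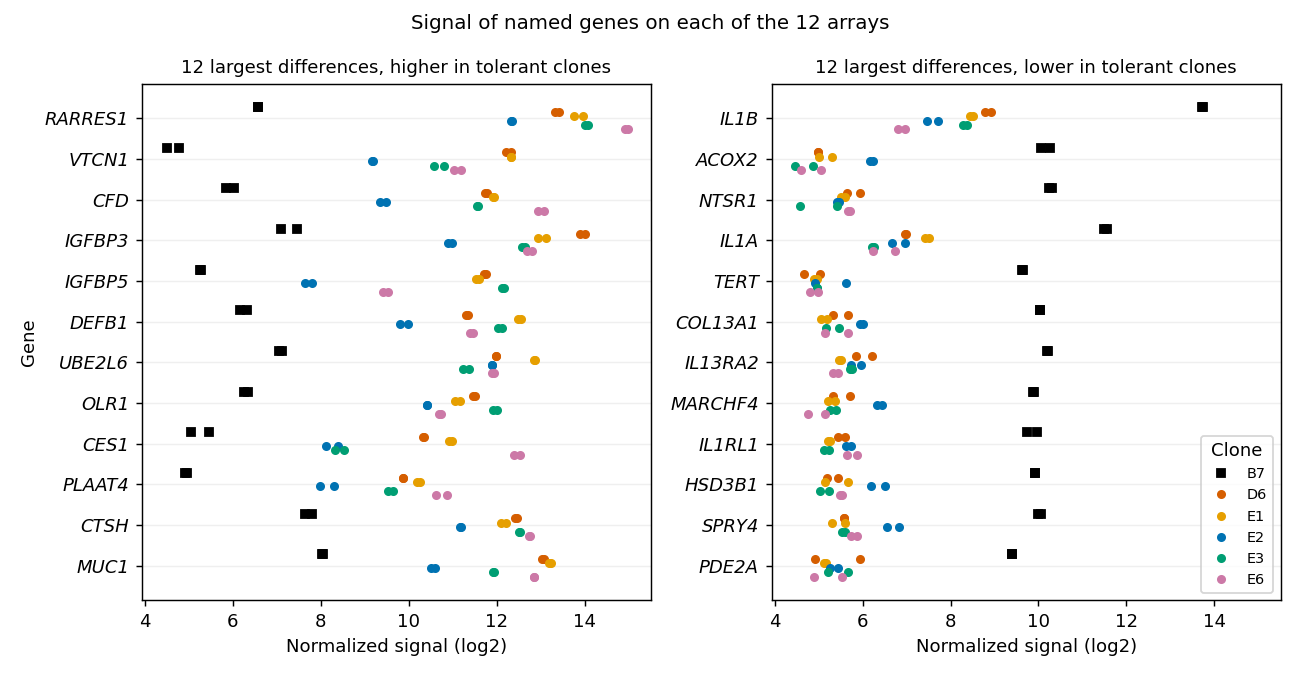
Normalized signal (log2, horizontal axis) of named genes on each of the 12 arrays, 1 point per array, colored by clone. The 5 tolerant clones lie above B7 for genes such as RARRES1 (13.72 on average against 6.58) and below it for genes such as IL1B (8.03 against 13.74).

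With the clone as the replicate, 171 genes were higher and 176 lower in the tolerant clones, 2.83% of the 12250 tested, and 165 and 168 of them by at least 2-fold. Taken in turn as the odd clone, each tolerant clone gave 0 genes by the same limma test, with 113 to 556 genes at an unadjusted p under 0.05 against 3089 for B7. B7 stands among the other 5 in these fits and widens their spread. With B7 left out, a comparison added after seeing the data, each tolerant clone against the other 4 again gave 0 genes, with 206 to 1950 at an unadjusted p under 0.05, most for E2. The counts rested on which clones were in the fit: 61 higher and 100 lower without D6, 83 and 97 without E1, 1050 and 1080 without E2, 33 and 49 without E3, and 32 and 54 without E6. With the authors' values 111 genes were higher and 167 lower, and with median scaling, which shifts the median of all genes by -0.20 log2 units, 132 were higher and 329 lower (28.6% higher against 49.3%). Of the 46 named genes called here, 19 lost the call without D6, 17 without E1, 0 without E2, 23 without E3 and 23 without E6. With the authors' values 19 lost it, with an offset of 50 7, with median scaling 5 and with the mean over a gene's probes 5. The call held under every alternative run for 22 of them: ACOX2, AKR1B10, COL13A1, CTSH, HSD3B1, IL13RA2, IL1A, IL1B, IL1RL1, IL24, JDP2, MARCHF4, MMP1, NTSR1, OLR1, PDE2A, PSMB10, RARRES1, SPRY4, TERT, UBE2L6 and UGT1A6.

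**Figure D2:**
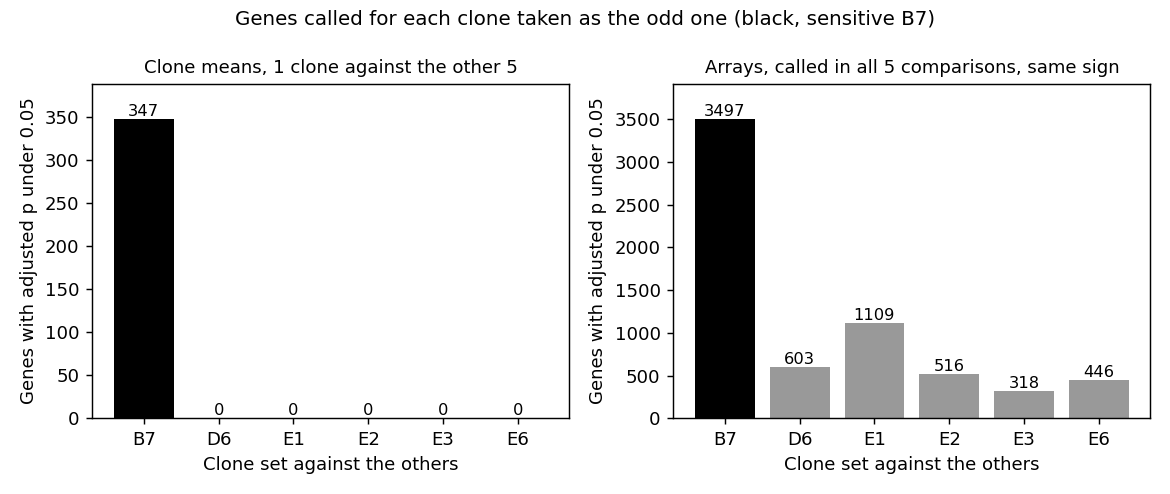
Number of genes with an adjusted p under 0.05 (vertical axis) when each clone (horizontal axis) is set against the other 5, with clones as replicates and at the array level in all 5 comparisons. B7 gave 347 and 3497 genes, and the tolerant clones gave 0 genes and 318 to 1109 genes.

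Part of the genes that report the output of the ERK pathway, which lies downstream of EGFR, were lower in the tolerant clones. Of 24 measured, 8 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -1.81 log2 units (camera adjusted p = 3.0e-09; adjusted p = 0.782 with an estimated correlation). The phosphatase DUSP6 differed by -4.03 ± 0.66 (adjusted p = 0.0323), beside SPRY4. The AP-1 member FOSL1 was 8.02-fold lower (SE 0.48 log2 units, adjusted p = 0.03) and the ETS factor ETV4 8.01-fold lower (SE 0.49, adjusted p = 0.0326). In D6, E1, E3 and E6 FOSL1 stood at 5.90 to 6.42 log2 units and ETV4 at 5.75 to 6.52. These levels are near the background, so the sizes of both folds are uncertain. Other probes differed by -3.23 for DUSP6 and -2.68 for ETV4. Against B7 the list was lower in each clone by a median of -1.28 (D6) to -2.24 (E3). In the EGFR family list, the ligand HBEGF fell by 3.40 ± 0.56 (adjusted p = 0.0333) and the receptor ERBB3 rose by 1.67 ± 0.30 (adjusted p = 0.038), while 8 of the 10 measured genes did not pass. The list as a whole had a median of -0.54 (camera adjusted p = 0.30; 2 higher and 4 lower adjusted over the list alone). The other probes of ERBB3 differed by 0.35 and 0.16.

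In the list of antigen presentation on MHC class I, 4 of 21 measured genes were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 6.2e-05; adjusted p = 0.782 with an estimated correlation). The 4 were the immunoproteasome subunits PSMB9 (at least 3.51-fold, adjusted p = 0.0353), PSMB10 (1.69 ± 0.21, adjusted p = 0.0161) and PSMB8 (1.62 ± 0.25, adjusted p = 0.025) and the activator PSME1 (1.36 ± 0.19, adjusted p = 0.0192). The probe used for PSMB9 was detected on 0 B7 arrays and its other probe on 1. Other probes differed less for PSMB9 (0.47), PSME1 (0.35) and PSMB8 (0.34), and 2 further probes of PSMB8 differed by 1.67 and 1.86. In the interferon response list, 2 of 31 were higher and 0 lower (4 and 0 adjusted over the list alone; median 0.61, camera adjusted p = 0.00207; adjusted p = 0.782 with an estimated correlation), UBE2L6 and the transcription factor IRF1 (1.89 ± 0.36, adjusted p = 0.0483). In the list of inflammatory genes, 3 of 31 were higher and 4 lower (7 and 4 over the list alone; camera adjusted p = 0.245). Beside IL1A and IL1B, the acute phase gene SAA1 rose by 2.82 ± 0.50 (adjusted p = 0.039), and the cytokine IL24, detected on 0 tolerant arrays, was at least 2.62-fold lower (adjusted p = 0.0083). Other probes differed by 1.99 and 1.29 for SAA1 and by -0.87 for IL24.

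In the list of detoxification genes under NRF2 control, 3 of 32 were higher and 0 lower (9 and 2 adjusted over the list alone; median 0.43, camera adjusted p = 0.0106; adjusted p = 0.782 with an estimated correlation). They were UGT1A6 (3.76 ± 0.22, adjusted p = 0.00142), whose probes can share exons with other UGT1A genes, the aldo-keto reductase AKR1B10 (2.54 ± 0.32, adjusted p = 0.0156) and the glutathione transferase GSTM1 (1.63 ± 0.25, adjusted p = 0.0264). In the integrated stress list, 1 of 33 was higher and 0 lower (1 and 0 over the list alone; median 0.34, camera adjusted p = 0.031; adjusted p = 0.782 with an estimated correlation), the AP-1 repressor JDP2 (2.22 ± 0.24, adjusted p = 0.00997). Among metallothioneins 1 of 7 was lower and 0 higher (4 and 0 over the list alone; median -0.92, camera adjusted p = 0.0348; adjusted p = 0.782 with an estimated correlation), MT1G (-2.99 ± 0.55, adjusted p = 0.0427). Among epithelial genes 1 of 28 was higher and 0 lower (2 and 0 over the list alone; median 0.55, camera adjusted p = 0.0367; adjusted p = 0.782 with an estimated correlation), the transcription factor ELF3 (3.36 ± 0.61, adjusted p = 0.0411). Clone by clone against B7, several of these lists did not pass camera with its preset correlation. They were epithelial genes in E2 (median 0.05, 8 higher and 11 lower, adjusted p = 0.895), metallothioneins in D6 and E1 (3 higher and 4 lower in each, adjusted p = 0.303 and 0.842), integrated stress in E3 and E6 (adjusted p = 0.378 and 0.212) and NRF2 targets in D6 (adjusted p = 0.099). Over the alternatives run, the medians ranged from 0.24 to 0.80 for interferon response, 0.22 to 0.48 for NRF2 targets, 0.20 to 0.45 for integrated stress, 0.21 to 0.71 for epithelial genes and -1.30 to -0.80 for metallothioneins. Of 26 alternatives, 7 ended the call of the epithelial list and 7 that of metallothioneins, 4 that of integrated stress, and 2 each those of interferon response and NRF2 targets. In the heat shock list 2 of 14 were lower and 0 higher (6 and 1 over the list alone; median -0.54, camera adjusted p = 0.0596), the cochaperone BAG3 (-1.64 ± 0.23, adjusted p = 0.021) and HSP90AB1 (-1.14 ± 0.17, adjusted p = 0.0243).

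The cell cycle lists were lower in 4 of the tolerant clones and not in E2. Of 37 mitosis genes, 0 passed between clones (0 over the list alone), with a median of -1.44 (camera adjusted p = 5.6e-06; adjusted p = 0.782 with an estimated correlation). The largest values were those of KIF4A (-2.20 ± 0.94, adjusted p = 0.203) and FOXM1 (-2.11 ± 0.78, adjusted p = 0.158). Against B7, all 37 were lower in D6, E1, E3 and E6 at the array level, with medians of -2.38, -1.63, -1.60 and -1.26, while E2 had a median of -0.02 with 5 higher and 8 lower (camera adjusted p = 0.895). Of 31 S phase genes, 1 fell, the cyclin CCNE1 (-2.05 ± 0.35, -0.38 at another probe, adjusted p = 0.0363; 1 lower over the list alone), with a median of -1.08 (camera adjusted p = 6.0e-05; adjusted p = 0.782 with an estimated correlation). Against B7 the S phase medians were -2.03 in D6, -1.68 in E1, -1.14 in E3 and -0.84 in E6, and -0.10 in E2 (camera adjusted p = 0.167). The brightness of the arrays went with these lists, with 75th percentiles of 131 in B7, 118 in E2 and 80.2 to 104 in the other clones.

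In the mesenchymal list, 1 of 22 was higher and 1 lower (1 and 1 adjusted over the list alone; median 0.08, or -0.0486 with median scaling, camera adjusted p = 0.405). The clones differed in direction: against B7 its median was 0.59 in D6, 0.65 in E1 and 0.09 in E3, but -0.18 in E2 and -0.26 in E6. TPM1, a tropomyosin, rose by 1.47 ± 0.19 (adjusted p = 0.0163), and the collagenase MMP1, detected on 0 tolerant arrays, was at least 2.43-fold lower (adjusted p = 0.0123). In the list of stem cell and persister markers, 1 of 15 was higher and 1 lower (2 and 1 over the list alone; median 0.25, camera adjusted p = 0.579), the dehydrogenase ALDH3A1 (3.36 ± 0.57, adjusted p = 0.034) and the integrin ITGA6 (-2.63 ± 0.48, adjusted p = 0.0416). Of the 36 lists, 9 passed camera with its preset correlation, 5 higher and 4 lower. With an estimated correlation 0 passed, each of the 9 at adjusted p = 0.782, and fry called 3: ERK output (adjusted p = 0.0404), heat shock (adjusted p = 0.0404) and WNT signalling (adjusted p = 0.0469), in which 1 of 24 was higher and 2 lower. In 5 other lists, none of which passed, the median, the mean and the direction of camera's test differed in sign. Against B7, clone by clone over arrays, the ERK list passed camera with an estimated correlation (adjusted p = 0.00451 to 0.0205). These p-values measure only the spread between a clone's 2 arrays, and all share the B7 arrays. The same test called mitosis in D6, E1, E3 and E6 (adjusted p = 0.00141 to 0.00368) but not E2 (0.893). It called MHC class I in D6, E1, E2 and E6 (adjusted p = 0.0256 to 0.0481) but not E3 (0.0549). Interferon response passed it in D6, E1 and E6 but not in E2 (0.0846) or E3 (0.107). Epithelial genes passed in D6, E1 and E6 but not in E2 (0.908) or E3 (0.107). NRF2 targets passed only in E6 (0.0481), integrated stress in D6, E1 and E2, and metallothioneins in E2 and E6.

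**Figure D3:**
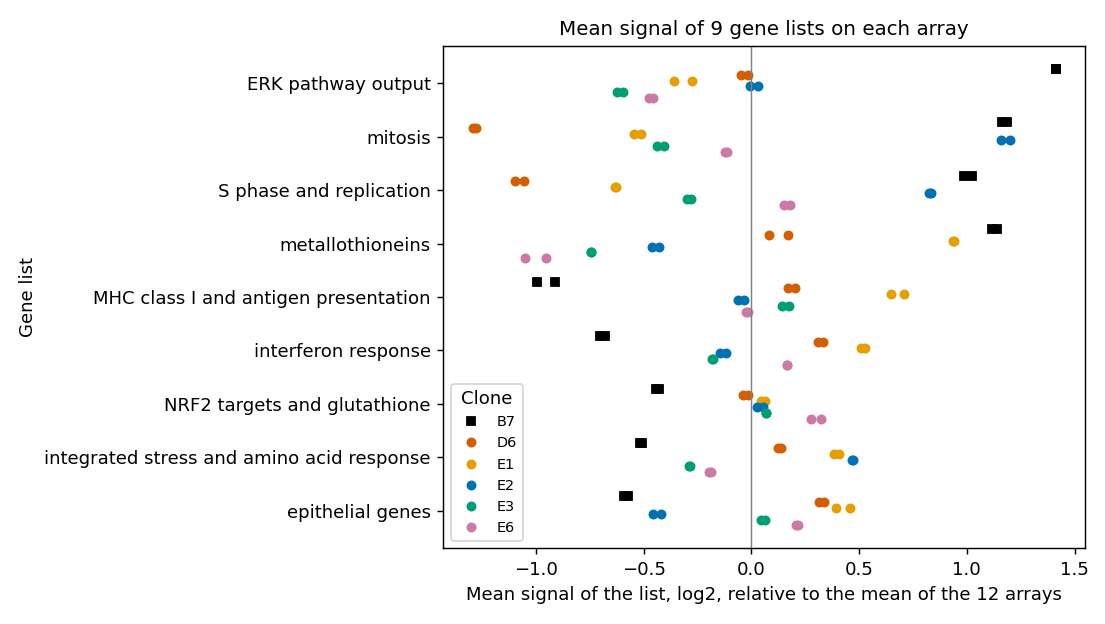
Mean signal of 9 gene lists (log2, relative to the mean of the 12 arrays, horizontal axis) on each array, colored by clone. In the mitosis list E2 lies at 1.18 beside B7 at 1.17, while D6, E1, E3 and E6 lie between -1.29 and -0.12.

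The genes set beforehand to be given whatever their values did not pass between clones in the main fit, each at its brightest probe. EGFR differed by -0.76 ± 0.87 (adjusted p = 0.621), with 10.45 log2 units in B7, 11.21 in E1, 10.17 in D6, 9.52 in E2, 8.90 in E3 and 8.64 in E6. A dimmer EGFR probe differed by -1.51 (adjusted p over probes 0.0333) and another by -0.23. AXL, a receptor kinase, differed by -0.81 ± 0.43 (adjusted p = 0.28), and stood at 8.88 in E6 against 9.85 to 10.02 in the other tolerant clones. The receptor kinase MET differed by -0.39 ± 0.18 (adjusted p = 0.224), with -0.31 to -0.51 in the single clones, and the cell death gene BCL2L11 by -0.17 ± 0.24 (adjusted p = 0.696). The mesenchymal filament VIM differed by -0.29 ± 0.48 (adjusted p = 0.744), with 0.59 in D6 and -0.72 in E2 against B7. The cadherin CDH1 differed by 0.89 ± 0.45 (adjusted p = 0.264), with 1.42 in E1 and 0.06 in E2.

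Each tolerant clone against B7, tested over arrays, gave many more genes. The calls were 3916 higher and 3966 lower in D6, 3970 and 4055 in E1, 2993 and 2776 in E2, 3619 and 3677 in E3, and 3687 and 3828 in E6. With a difference of at least 2-fold they were 1228 and 1144, 1452 and 1259, 463 and 394, 980 and 908, and 1105 and 931. With median scaling 24.4 to 36.9% of a clone's calls were higher, against 49.1 to 51.9%. In all 5 clones, 1787 genes were higher and 1710 lower, among them every one of the 347 called between clones. Independent lists of these sizes would share 27.6 and 27.9 genes. The 5 comparisons share B7, whose 2 arrays cannot be divided among them, so part of the excess may come from it. Simulations with no effect, shared B7 arrays and no spread between clones gave 0 genes. With B7 drawn from the tolerant clones' own spread they gave 448 higher and 446 lower on average. With median scaling the counts in all 5 clones were 1070 and 2754.

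The tolerant clones also differed from one another, at 8938 genes (73.0%, moderated F test over arrays). Set against the mean of the other 4 tolerant clones, E2 differed most, with 3238 genes higher and 3277 lower, and E3 least, with 1897 and 1991. In E2 the mitosis list was higher (37 of 37 genes, median 1.75, camera adjusted p = 0.000677 with an estimated correlation) and so was the S phase list (30 of 31, median 1.29, adjusted p = 0.000917), in the brightest of the tolerant clones. The examples were CENPA, the centromeric histone (2.36 ± 0.09), KIF4A (2.21 ± 0.18), BIRC5 (2.20 ± 0.07) and CDCA3 (2.16 ± 0.08) for mitosis, and CDC45 (2.10 ± 0.08), GINS2 (2.03 ± 0.07), MCM10 (1.89 ± 0.06) and MCM4 (1.74 ± 0.09) for replication. Epithelial genes were lower in E2 (21 of 28, 1 higher, median -0.59, adjusted p = 0.0161), with PRSS8 (-2.32 ± 0.13), MUC1 (-2.22 ± 0.06), CLDN1 (-1.77 ± 0.07) and JUP (-1.29 ± 0.06). Mesenchymal genes were lower in E2 as well (16 of 22, 2 higher, median -0.65, adjusted p = 0.0161). By the same test they were also lower in E6 (15 of 22, 1 higher, median -0.52, adjusted p = 0.00936). They were higher in D6 (13 of 22, 4 lower, median 0.46, adjusted p = 0.0211) and E1 (14 of 22, median 0.49, adjusted p = 0.0168). Amino acid response genes were higher in E2 (21 of 33, 5 lower, median 0.44, adjusted p = 0.0161), with PSAT1 (1.95 ± 0.06), ASNS (1.73 ± 0.06), PHGDH (1.31 ± 0.07) and MTHFD2 (1.30 ± 0.07). That list was higher in E1 too (20 of 33, 6 lower, median 0.27, adjusted p = 0.0331). It was lower in E3 (24 of 33, 3 higher, median -0.51, adjusted p = 0.00575) and E6 (22 of 33, 2 higher, median -0.37, adjusted p = 0.00679). The most different single genes in E2 were ALOX5AP, the activator of 5-lipoxygenase (3.08 ± 0.07), LTB (2.88 ± 0.09) and FABP5 (2.87 ± 0.14), and in the other direction IGFBP5 (-3.50 ± 0.06), CLIC3 (-3.04 ± 0.09) and PLA2G10 (-3.02 ± 0.09).

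In D6, 2226 genes were higher and 2423 lower than in the other 4. Mitosis genes were lower still (37 of 37, median -1.35, adjusted p = 0.00041 with an estimated correlation), with NUSAP1 (-1.91 ± 0.07), TOP2A (-1.88 ± 0.06), CDK1 (-1.82 ± 0.07) and CDCA3 (-1.79 ± 0.08), in the clone with the dimmest arrays. Squamous and basal genes were higher (14 of 20, 2 lower, median 0.63, adjusted p = 0.0492), with the serpins SERPINB4 (3.29 ± 0.12) and SERPINB3 (3.26 ± 0.11) and the keratins KRT13 (2.87 ± 0.09) and KRT15 (1.78 ± 0.10). SERPINB4 and KRT13 were each detected on 5 of the 8 arrays of the other clones. CCN2, a matricellular protein, was higher by 3.19 ± 0.19, and MUC4 (-2.66 ± 0.06), CDC45 (-2.07 ± 0.08) and CDCA7 (-1.99 ± 0.06) were lower. The 2 other probes of MUC4 stood at 6.08 and 6.29 in D6, within the range of the other tolerant clones, and with the mean over its probes MUC4 differed by -0.90. In E1, with 2939 higher and 2728 lower, hypoxia and glycolysis genes were higher (30 of 34, median 0.75, adjusted p = 0.00329), with CA12 (2.81 ± 0.13), ANKRD37 (2.43 ± 0.09), ENO2 (2.43 ± 0.11) and ERO1A (2.20 ± 0.11). CA12 and ENO2 were detected on 2 and 3 of the 8 arrays of the other clones. Metallothioneins were also higher (6 of 7, 1 lower, median 1.63, adjusted p = 0.0354), with MT1X (3.29 ± 0.07), MT1F (2.58 ± 0.07), MT2A (1.73 ± 0.07) and MT1H (1.63 ± 0.08), the last detected on 2 of the other 8 arrays. The smooth muscle actin ACTG2 (3.70 ± 0.07) and DEPP1 (3.0 ± 0.07) were higher in E1, and LFNG (-1.93 ± 0.07) and SNAR-A1 (-1.91 ± 0.18) were lower. PYCARD, the inflammasome adaptor, was not detected in E1 and was at least 5.33-fold lower there. The second probe of LFNG stood at 5.81 in E1 and at 5.79 to 6.12 in the other tolerant clones, and with the mean over probes LFNG differed by -1.04 and PYCARD by -1.93.

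In E3 the hypoxia and glycolysis list was lower (27 of 34, 1 higher, median -0.48, adjusted p = 0.00269 with an estimated correlation), with NDRG1 (-2.19 ± 0.06), HK2 (-1.58 ± 0.07), SLC2A3 (-1.44 ± 0.06) and ENO2, not detected in E3 and at least 2.40-fold lower. The same list was also lower in E2 (20 of 34, median -0.44, adjusted p = 0.0161) and E6 (23 of 34, median -0.26, adjusted p = 0.00679) and higher in D6 (21 of 34, median 0.48, adjusted p = 0.0039). Its mean level, relative to all arrays, was 0.83 in E1 and 0.53 in D6, against -0.46 in E3, -0.35 in E2, -0.34 in B7 and -0.21 in E6. The elongation factor EEF1A2 (-4.25 ± 0.07, detected on 1 E3 array) and VCX2 (-4.09 ± 0.09) and VCX (-3.84 ± 0.07), members of a family with near-identical sequences, were lower in E3. LOXL4 (2.34 ± 0.09), SPRR3 (2.10 ± 0.10) and IGFBP5 (2.02 ± 0.06) were higher. In E6, with 2023 genes higher and 2003 lower, NRF2 targets were higher (16 of 32, 2 lower, median 0.21, adjusted p = 0.0318), with GPX2 (2.14 ± 0.07), GCLC (0.93 ± 0.07), ABCC2 (0.75 ± 0.10) and AKR1B10 (0.65 ± 0.06). FSTL5, detected in E6 and on 0 arrays of the other 4 clones, was at least 6.28-fold higher, beside CES1 (2.97 ± 0.11) and the ribosomal RNA gene RNA5S9 (2.88 ± 0.10). ACTG2 (-3.26 ± 0.07) and ALOX5AP (-2.88 ± 0.07) were lower in E6, and the glypican GPC4, not detected there, was at least 3.71-fold lower. Of the 36 lists, 8 passed in D6, 10 in E1, 7 in E2, 6 in E3 and 6 in E6 with an estimated correlation. The lists described for a clone were chosen among these after their values were seen. Of the list results given here, 14 were rerun under the alternatives. The mesenchymal results in D6, E1 and E6 and the amino acid results in E1, E3 and E6 were not. With median scaling 0 of the 14 passed with an estimated correlation, although all kept their direction. Several kept their size, such as mitosis in E2 (1.96) and D6 (-1.51), S phase in E2 (1.56) and hypoxia in E1 (0.70). Others shrank, such as epithelial genes in E2 (-0.37) and squamous genes in D6 (0.37). None of the 19 alternatives run left out a clone. Under them NRF2 targets in E6 lost the call in 13, squamous genes in D6 in 11 and metallothioneins in E1 in 9. All these single genes passed the array-level test, and ± gives the SE from arrays.

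Markers of other cell types were detected in part. Of those with a probe, 2 of 9 fibroblast, 6 of 10 leukocyte, 2 of 7 endothelial and 1 of 5 erythroid markers passed the detection filter. PTPRC, CD3E and CD3D were detected on 0 arrays. CD14, LYZ, CD68, CSF1R, COL1A1, PECAM1 and CDH5 were detected on all 12. COL1A1 (1.56 ± 0.65, adjusted p = 0.196), CSF1R (1.43 ± 0.58, adjusted p = 0.185), CD14 (1.22 ± 0.45, adjusted p = 0.156) and CDH5 (adjusted p = 0.177) had higher means in each tolerant clone than in B7 without passing between clones. FCER1G, detected only in B7, was lower in the tolerant clones (adjusted p = 0.00784).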

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

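The tests of array brightness, of other splits of the clones and of RNA mixed into E2 were chosen after the results they address were seen, and the test of gene neighbours for B7 before.

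B7 stood apart from the 5 tolerant clones at 347 genes. Array brightness as it varies between the arrays of a clone is argued against as the cause, since its slope there, carried on to B7's brightness, gives a share of 0.0304 of the differences (-0.0111 to 0.0719 at 2 SE, and -0.201 to 0.148 without E6). Brightness that goes with the clone cannot be told apart. Each tolerant clone was held out while genes were called between the other 4 and B7, and its position between them followed its brightness at a slope of 0.153 (-0.182 to 0.488 at 2 SE), but 0.565 without D6. E2 stood at 0.457 of the way to B7 where its brightness gives 0.679. Altered dosage of chromosome segments in B7 is argued against only as the source of the size of these differences. The 20 tested neighbours of each called gene differ in median by 0.0175 of the gene's own difference (95% bootstrap interval 0.00198 to 0.0266). Called genes were picked for large differences, so segment-wide shifts much smaller than these could not be seen by that share. Of the 6 splits of 1 clone against 5, only 1 gave as many genes, the real one with 347 against a highest other count of 0, and 6 splits are too few for a share under 0.05. In the other splits B7 itself widens the spread. Drug exposure and response, which the design confounds, stay open. So do brightness between clones, smaller shifts of segment dosage and anything else particular to the single sensitive clone.

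E2 lay beside B7 in the cell cycle genes while its ERK output genes lay 20.8% of the way to B7. It was also near B7 in lists outside the cell cycle, such as epithelial (82.8%) and squamous genes (78.9%). In hypoxia and glycolysis it stood at 102%, but nearness to B7 there was not particular to E2. That list's mean was -0.34 in B7, -0.35 in E2, -0.46 in E3 and -0.21 in E6, against 0.53 in D6 and 0.83 in E1. Other lists lay far from B7 in E2, such as NRF2 targets (10.7%), MHC class I (24.9%) and integrated stress (-87.4%). Array brightness as it varies between the arrays of a clone is argued against as the cause of the cell cycle result. Between those arrays the mitosis list changed by -0.0896 per log2 unit of brightness (-0.462 to 0.282 at 2 SE), against 3.76 between clones. That slope rests mainly on E6, whose arrays differ most in brightness, and without E6 it is -0.749 (-2.25 to 0.754), still under the 1.88 that would be needed for an effect of 0.5 of the slope between clones. B7 cells or RNA mixed into E2 are argued against by the 80 genes at least 4-fold lower in the other 4 clones, whose median level in E2 was 8.67% of the way to B7 (5.55 to 11.5), while the mitosis genes stood at 97.9%. For the cell cycle genes alone, a candidate explanation is faster growth of E2 than of the other tolerant clones. Growth was not measured here. Brightness that goes with the clone, which arrays of the same clone cannot test, remains open and unexplained.

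In 6 of the 75 genes, lists and measures screened, 1 tolerant clone stood far from the other 4, where chance alone gives about 5%. The gap to the next clone, as a share of the whole range, was 0.732 for TERT, 0.763 for ERBB3, 0.759 for DUSP6 and 0.821 for FOSL1, all in E2 and all toward B7. It was 0.843 for PSMB9 in E1, the highest clone, and 0.849 for AXL in E6, the lowest. TERT was detected on 0 tolerant arrays, so its gap lies within background values.

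EGFR moved in opposite directions against B7 in E1 and E6, which differed by 2.57 log2 units (F test over the tolerant clones, adjusted p = 2.9e-08). VIM did so in D6 and E2, which differed by 1.31 log2 units (adjusted p = 3.4e-06). Of the 5492 detected probes with no assigned gene, left out of the comparisons, 78 passed the clone-level test, 32 higher and 46 lower in the tolerant clones.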

How the results depend on the processing

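Offset 50, 75th percentile scaling and leaving B7 out were chosen after seeing the data. Against the main 171 genes higher and 176 lower in the tolerant clones, median scaling gave 329 lower and the authors' values 111 higher, the array-level fit 4026 and 4066, and the clone as a random block 991 and 794. Leaving out 1 clone or array gave 32 to 1050 higher and 49 to 1080 lower, the extremes without E6, E3 and E2, with fewer clones or a smaller spread between them. In all 5 clones, median scaling gave 1070 higher and 2754 lower, and a minimum log2 difference of 1 gave 310 and 213. That minimum left 2372 genes in D6, 2711 in E1, 857 in E2, 1888 in E3 and 2036 in E6. The most genes for a tolerant clone as the odd one was 0, and 1 without background correction, 1 with the authors' values, 0 with B7 left out and 0 to 1 with an array left out (1 without the first E3 array). Of 36 lists, 0 passed camera with an estimated correlation and 3 passed fry. In the mesenchymal genes list, median differences, which no test called, turned to -0.0486 with median scaling and, with a clone or array left out, ran from -0.0181 (without D6) to 0.225 (without E6), and that of the stem cell and persister list from -0.128 (without E6) to 0.335 (without the first D6 array). Apart from the changes that follow from fewer clones, a stricter limit or another estimate of spread, the cause was not tested. Of the 347 genes, 303 kept call and sign without background correction, 289 with median scaling, 210 with the authors' values, 339 without the filter, 319 with the mean over probes, 286 with the offset of 50 and 313 with 75th percentile scaling. Named gene differences were the same side of the threshold in 2578 comparisons, lost it in 123, gained it in 7 and reversed in 0. All 67 named calls of a clone against the other 4 were kept under the alternatives run. For these calls no alternative left out a clone, so their dependence on which clones were in the fit was not tested. Of the 14 list calls of that kind that were rerun, made with an estimated correlation, median scaling lost 14, all with the same direction.

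The replicate numbers shared by the clones do not pair the arrays: the 15 correlations between clones of the difference between replicates lay between -0.0248 and 0.0543. With the replicate number as a block, the array-level fit gave 4023 higher and 4052 lower, and all 5 clones 1774 and 1706. A chip or slide block was not run, since the files give none. Signal over background limits the folds of genes under 20.1 to 24.1 intensity units.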

Other observations

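The test of each clone on its own scale was chosen after the result was seen, and the other tests of gene runs before.

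Runs of neighbouring genes shifted together in some clones. Among 6036 well expressed genes in 112 runs of at least 50 neighbours, 18 of 672 pairs of clone and run lay above the 95th percentile of that clone's largest run medians in 1000 shuffles of the gene order. The 50 genes from TSPAN6 to UTP14A were lower in E2 (median -0.33, 36 genes with that sign), and the 50 from FAM133B to PSMC2 lower in D6 (-0.30, 42 genes). Adjacent runs, NFKBIA to SIX4 (0.22, 43 genes) and MNAT1 to ACYP1 (0.25, 43 genes), were higher in E3, and CRBN to CMTM7 was higher in E1 (0.23, 40 genes). The 80 genes from TSC22D2 to RPL35A were lower in E2 (-0.21) and higher in E1 (0.16), and the 50 from FBXO11 to RAB11FIP5 higher in D6 (0.15) and lower in E3 (-0.13) and E6 (-0.12).

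On 1 scale for all clones, the largest run median was 0.331 against a 95th percentile of 0.330 and a highest value of 0.490 after shuffling, so chance arrangement cannot be told apart there, since B7's wide spread sets that scale. Each clone on its own scale, chance arrangement is argued against by 5 of the 6 clones, whose largest run lay above all of their own shuffles, and not by B7 (0.320, with 73 of 1000 shuffles as large). Of the shifted runs, 88.9% kept at least 0.25 of the shift in both parts without genes beyond 1 log2 unit. That says little on a few strongly regulated neighbours, since the runs were picked by a median that such genes hardly move. Under the authors' values 100% of shifted runs kept at least 0.5 of their shift, which argues against details of the normalization chosen here. Those values also rest on a factor that changes with intensity, so effects that both normalizations share were not tested. A candidate explanation is that clones differ in the copy number of chromosome segments. No DNA was measured, and no biological explanation was tested.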
